A study of Mus musculus with 96 samples.

How the data were processed

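Liver RNA from 96 male mice was measured on 96 single-colour Affymetrix Mouse 430 2.0 arrays, with 1 mouse on each array and no pooling per the labels. The mice came from 6 strains, namely 129S1/SvImJ, C57BL6/J, C3H/HeJ, CBA/J, DBA/2J and B6C3F1/J, the last being the first-generation cross of C57BL6/J and C3H/HeJ. Per the labels, mice arrived at 6 weeks of age, were housed alone and fed 84 kcal per week of a purified diet for 2 weeks, and from 8 weeks of age received either a control diet or a diet restricted by 25% in calories. Tissue was taken at 22 weeks of age, after 14 weeks on the diets. Each of the 12 combinations of strain and diet held 8 mice, and groups were taken from the labels.

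The deposited values are MAS5 signals, an intensity on a linear scale with no further unit. The authors made them from biotin-labelled cRNA prepared from total RNA. The trimmed mean of the arrays, with the highest and lowest 2% of probe sets left out, lies between 500 and 500.2, so each array had been scaled to about that level. No other normalization between arrays was visible in the values. The version and settings of MAS5 are not given in the sources used here.

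Signals were read into R 4.3.3 and turned into log2 values. Of 45101 probe sets, 64 control probe sets were left out. A probe set was kept when its signal was at or above the median of the array in at least 8 of the 96 arrays, which left 32999. The probe annotation gave a single gene symbol for 34958 probe sets, several for 932 and none for 9211. Of the first, 34754 were matched by gene identifier to the GRCm38.p6 gene table, which changed 0 symbols. Each gene was represented by its kept probe set with the highest mean log2 signal, which gave 14816 genes. Gene positions were not used here, and the genome build behind the array design is not given in the sources used here.

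All tests of genes were made with limma 3.58.1. A mean was fitted for each of the 12 groups with lmFit, and contrasts were tested with eBayes with an intensity trend and robust variances. Differences are log2(restricted) minus log2(control), with the SE of limma. P values were adjusted over all genes by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a call. The contrasts were the diet effect averaged over the 6 strains, the diet effect in each strain, an F test of the interaction of strain and diet, an F test over the 6 control groups with each strain against the mean of the other 5, all 15 pairs of control groups, and B6C3F1/J against the mean of its parents for the control level and for the diet effect. A gene was counted as changed in all 6 strains when it was called with the same sign in each.

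A total of 46 gene lists were fixed before the data were examined, covering metabolic pathways, sex-biased and stress genes, and markers of other cell types. The 45 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera asks whether a list moved more than other genes, and fry asks whether its genes moved on balance in 1 direction. List p values were adjusted over the lists of a contrast. Counts of list members are over all genes tested, and a further count was adjusted over the list alone.

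Named genes followed a rule fixed in the same way. For the averaged diet effect it took the 12 largest rises and 12 largest falls among calls with the same sign in all 6 strains, and up to 3 members of each list with the smallest p. Within each strain it took the 2 largest rises and 2 largest falls, for the interaction the 8 genes with the smallest p, for each strain on the control diet the 2 largest differences each way, and for B6C3F1/J the 3 largest each way. A set of metabolic, clock and growth genes was always named. Some genes of that set are not reported here.

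For each array the median log2 signal, the log2 difference between the 3' and 5' control probe sets of Gapdh and beta-actin, and the mean log2 signal of each marker list were computed. Diet differences in these measures were tested by two-sided permutation within strain, exact over all 12870 splits for a strain and with 100000 draws for the average of strains. The precision of all values is limited by the number of arrays.

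The alternatives were quantile normalization, centring each array on its 75th percentile, an offset of 8.55 (the 10th percentile of all signals), no filter and a stricter filter, the mean of a gene's probe sets, every probe set on its own, eBayes without trend and robust variances, limma arrayWeights, a fit of only the groups in a contrast, a 1.5-fold minimum and a block for replicate number. Further alternatives left out arrays with a median log2 signal above 8, used the array median as a covariate, or left out CBA/J. The gene and list tests were run on simulated log2 values of the filtered genes with known changes. Permutation tests and figures used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.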

Results

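Gene expression was measured in the liver of 96 male mice, 8 on a control diet and 8 on a diet restricted by 25% in calories in each of 6 strains, with 1 array per mouse. The design addresses how the liver transcriptome responds to 14 weeks of calorie restriction, and how gene levels and their response differ between strains. After filtering, 14816 genes were tested. Values are log2 signals, each difference is restricted minus control with its SE, and every group holds n = 8 mice unless stated. Where the mean signal of a group lay below the mean array median, the size of a difference from it is uncertain.

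The arrays were comparable in scale apart from a few. The median log2 signal of 94 arrays lay between 6.21 and 7.504, while it was 8.295 in DBA/2J restricted replicate 6 and 8.655 in B6C3F1/J control replicate 2. In CBA/J the 8 restricted arrays had a mean median of 7.29 against 6.52 in the 8 controls (exact permutation p = 0.00016, the smallest that 12870 splits can give; adjusted p = 0.0028 over 72 comparisons). The 3' minus 5' signal of Gapdh, a sign of RNA or labelling quality, was also higher in CBA/J restricted mice, at -0.03 against -0.40 (exact permutation p = 0.00016, adjusted p = 0.0028). Averaged over strains, the diet difference of the array median was 0.12 (permutation p = 0.076, adjusted p = 0.18 over 12 measures). Pairs of arrays within a group correlated across genes with a median r of 0.909, with a lowest r of 0.445. Genes are not independent replicates in such an r.

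**Figure D1:**
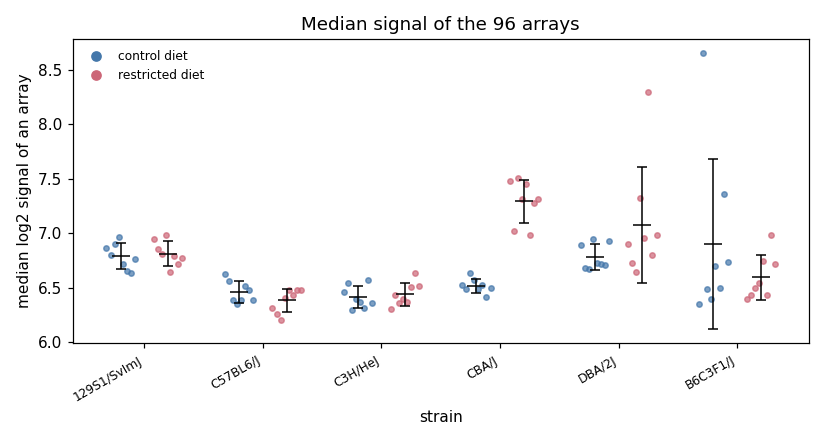
Each point is the median log2 signal of 1 array, by strain and diet, and bars give the mean and SD of 8 arrays. The CBA/J restricted arrays sit around 7.29, and 2 arrays lie apart at 8.295 and 8.655.

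Averaged over the 6 strains, restriction raised genes of fatty acid and sterol synthesis and of the female liver pattern. Genes of the male liver pattern and of fatty acid oxidation were lower, but both list calls were lost with an estimated correlation (adjusted p = 0.0593 and 0.0940). The largest rise was in Nnmt, which methylates nicotinamide, at 9.59-fold (log2 3.26 ± 0.16 SE, adjusted p = 2.79e-30). Gstm3, a glutathione transferase, rose 7.68-fold (log2 2.94 ± 0.16), and Acacb, which makes malonyl-CoA at mitochondria, rose 5.75-fold (log2 2.52 ± 0.23). The female-predominant enzymes Cyp2b13 and Cyp2b9 rose 7.29-fold and 5.34-fold, and Hao2, a peroxisomal oxidase, rose 5.94-fold. These folds are uncertain in size, since control levels lay below the mean array median in all strains for Cyp2b13, in 129S1/SvImJ, C57BL6/J, CBA/J and DBA/2J for Hao2 (3.995 to 4.82), and in 129S1/SvImJ and DBA/2J for Cyp2b9. The largest fall was in Hsd3b5, a male-specific steroid enzyme, which was 6.04-fold lower (log2 -2.60 ± 0.21, adjusted p = 1.05e-18). Serpina12, the adipokine vaspin, was 4.74-fold lower (log2 -2.25 ± 0.17), and Csad, an enzyme of taurine synthesis, was 3.74-fold lower (log2 -1.90 ± 0.11). In all, 2246 genes rose and 1840 fell, of which 582 and 295 changed at least 1.5-fold. With every probe set tested on its own, 1255 genes had several probe sets called in this average. Of these, 108 (8.606%) had them called in opposite directions, against at most 2.817% in single strains other than CBA/J and 24.91% in CBA/J. The count without CBA/J, an alternative chosen after the data were seen, was 1387 and 1202, and 2250 of the 4086 genes were called with the same sign in it.

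The other genes among the 12 largest rises were Slc22a27, an organic anion transporter (log2 2.25), Fdps of sterol synthesis (2.11), the fatty acid synthase Fasn (2.06), Cyp2b10 (2.03), the interferon-inducible Ifi27l2b (2.00) and the acetyl-CoA synthetase Acss2 (1.97). The other large falls were in Serpina4-ps1, a serpin pseudogene (log2 -2.56), the acyl-CoA thioesterase Acot1 (-1.93), the acetylcholine receptor subunit Chrna2 (-1.91), the pantetheinase Vnn1 (-1.89), the male-predominant Cyp4a12a (-1.77), the lysosomal nuclease Dnase2a (-1.75), Cyp4a14, an omega-hydroxylase of fatty acids (-1.52), Paqr9 (-1.52) and the interferon-stimulated Ifit1 (-1.51). Control levels lay below the mean array median in all strains but B6C3F1/J for Cyp2b10 (4.32 to 5.63), in 129S1/SvImJ, CBA/J and DBA/2J for Slc22a27 and in B6C3F1/J for Ifi27l2b. Restricted levels did so in 129S1/SvImJ, C57BL6/J, CBA/J and DBA/2J for Chrna2 (5.95 to 6.71) and in CBA/J for Dnase2a. By the rule that picked them, these 24 genes had the same sign in all 6 strains, and within single strains they passed the test in 3 to 6. A shared sign can rest on a small effect, such as -0.03 for Cyp4a12a in the strain with its smallest fall. The size of the response varied between strains for several. Cyp2b13 rose by 0.09 in the strain with the smallest effect and by 6.26 in C3H/HeJ (interaction adjusted p = 3.60e-08), from control levels of 4.23 to 5.45 that lay below the mean array median in every strain, and Nnmt by 1.64 to 4.88 (interaction adjusted p = 5.00e-06).

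**Figure D2:**
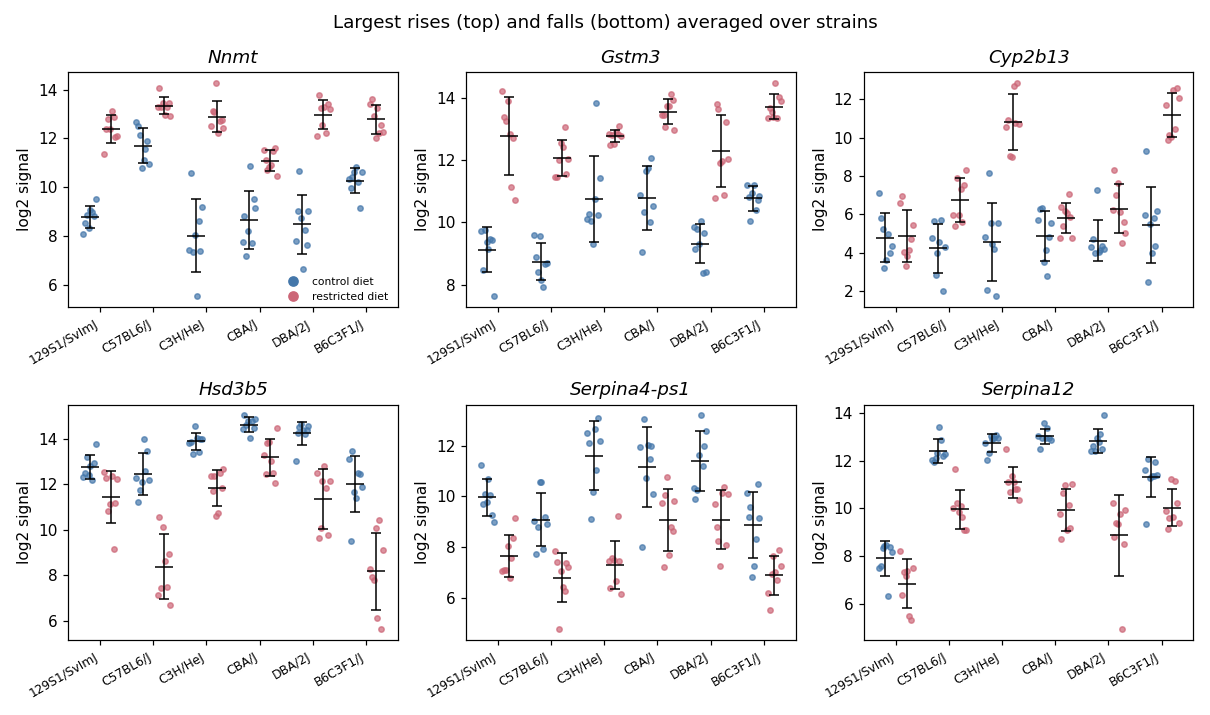
Log2 signal of the 3 genes with the largest rises and the 3 with the largest falls, by strain and diet, with 1 point per mouse and the mean and SD of 8 mice. Nnmt was higher on restriction in every strain, and Hsd3b5 was lower in every strain.

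Fatty acid and sterol synthesis rose as groups. Of 21 measured genes of fatty acid and triglyceride synthesis, 18 rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 difference of 0.96 (camera adjusted p = 1.61e-21). Members included Acss2, the citrate lyase Acly (log2 1.80 ± 0.14), the acetyl-CoA carboxylase Acaca (1.62 ± 0.13) and Srebf1, the transcription factor of lipid synthesis (1.02 ± 0.12). The desaturase Scd1 rose by 0.34 ± 0.10, but lost its call under quantile normalization (adjusted p = 0.241) and without CBA/J (0.10 ± 0.12, adjusted p = 0.652). Of 20 genes of cholesterol synthesis, 16 rose and 0 fell (17 and 0 adjusted over the list alone; median 0.76, camera adjusted p = 1.61e-18), among them Pmvk (1.66 ± 0.11), Nsdhl (1.49 ± 0.12) and Lss (1.42 ± 0.11). Both lists held with an estimated correlation (adjusted p = 0.0123 and 0.0392).

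Sex-biased liver genes moved apart. Of 15 measured female-biased genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.76 (camera adjusted p = 3.88e-07, and 0.000280 with an estimated correlation). Of 16 male-biased genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 1.45e-06; adjusted p = 0.0593 with an estimated correlation). Slco1a1, a male-biased organic anion carrier, fell by 1.20 ± 0.12 and Cyp7b1, an oxysterol hydroxylase, by 1.05 ± 0.12. Elovl3, a male-biased fatty acid elongase, fell by 0.71 ± 0.10.

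Genes of fatty acid oxidation and PPAR-alpha targets fell, with 20 of 30 lower and 2 higher (20 lower and 3 higher adjusted over the list alone; median -0.46). The camera adjusted p was 9.18e-14, and the adjusted p was 0.0940 with an estimated correlation. Slc25a20, the mitochondrial carnitine carrier, fell by 0.71 ± 0.07 and the hepatokine Fgf21 by 0.80 ± 0.14, while Cpt1a, which controls fatty acid entry into mitochondria, differed by 0.07 ± 0.10 (adjusted p = 0.654). Another probe set of Cpt1a was called in the opposite direction.

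Carbohydrate and amino acid metabolism rose. In gluconeogenesis 9 of 12 genes rose and 2 fell, also adjusted over the list alone (median 0.51, camera adjusted p = 1.27e-05; adjusted p = 0.137 with an estimated correlation). Got1, an aspartate aminotransferase, rose by 1.85 ± 0.19, the glucose-6-phosphatase G6pc by 0.57 ± 0.13 and Pck1, which makes phosphoenolpyruvate, by 0.51 ± 0.11. Pck1 lost its call without CBA/J (0.32 ± 0.13, adjusted p = 0.0768). In glycolysis and glucose uptake 6 of 10 rose and 1 fell (7 and 1 adjusted over the list alone), with Pgam1 at 0.60 ± 0.06 and Pklr at 0.77 ± 0.08 (median 0.28, camera adjusted p = 0.00280; adjusted p = 0.460 with an estimated correlation). Of 26 genes of amino acid breakdown and the urea cycle, 19 rose and 0 fell (21 and 0 adjusted over the list alone; median 0.39, camera adjusted p = 6.34e-12; adjusted p = 0.140 with an estimated correlation). Prodh, which oxidises proline, rose by 0.86 ± 0.08 and Cps1, the first enzyme of the urea cycle, by 0.77 ± 0.08. Periportal hepatocyte genes rose in 8 of 11 and fell in 1, also adjusted over the list alone, with Etnppl at 1.35 ± 0.10 and Asl at 0.84 ± 0.09 (median 0.51, camera adjusted p = 0.000304; adjusted p = 0.140 with an estimated correlation). Asl, Arg1, Pck1 and other urea-cycle and gluconeogenic genes also stand in the periportal list.

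Energy and signalling groups moved by less. Of 32 genes of oxidative phosphorylation, 19 rose and 0 fell (20 and 0 adjusted over the list alone; median 0.23, camera adjusted p = 1.45e-06; adjusted p = 0.460 with an estimated correlation), with the complex I subunit Ndufv1 at 0.56 ± 0.07. Sirtuins and NAD metabolism had 8 of 15 higher and 1 lower, also adjusted over the list alone (median 0.23, camera adjusted p = 0.0156; adjusted p = 0.460 with an estimated correlation). That list holds Nnmt, and the deacylase Sirt5 rose by 0.49 ± 0.11, while Sirt1 differed by -0.21 ± 0.12 (adjusted p = 0.191). Ppargc1a, a coactivator of mitochondrial genes, rose by 0.47 ± 0.09. In insulin and FOXO signalling 7 of 15 rose and 2 fell (8 and 3 adjusted over the list alone), with Ppp1r3g, a glycogen-targeting subunit, at 1.88 ± 0.17, the secreted binding protein Igfbp1 at 1.55 ± 0.13 and Foxo1 at 0.64 ± 0.11. Its camera adjusted p was 0.0163, and the adjusted p was 0.401 with an estimated correlation. The call ended without B6C3F1/J control replicate 2 (adjusted p = 0.0520), with the mean of a gene's probe sets (0.0824) and with every probe set on its own (0.159). Glucocorticoid targets rose in 7 of 16 and fell in 0 (8 and 0 adjusted over the list alone), among them Tat (1.01 ± 0.14) and the metallothioneins Mt2 (1.09 ± 0.17) and Mt1 (0.84 ± 0.14). That list had a camera adjusted p of 0.0164 (adjusted p = 0.460 with an estimated correlation, and 0.08 with every probe set on its own), while Fkbp5 differed by 0.15 ± 0.12.

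Stress and protein quality groups fell. Of 17 cytosolic heat shock proteins, 12 fell and 1 rose (13 and 2 adjusted over the list alone), with Hsph1 at -1.14 ± 0.11 and Hsp90aa1 at -1.12 ± 0.09 (median -0.45, camera adjusted p = 9.69e-11, and 0.0392 with an estimated correlation). Among endoplasmic reticulum chaperones and the unfolded protein response 9 of 22 fell and 4 rose (10 and 4 adjusted over the list alone), with Dnajb9 at -0.77 ± 0.09 and Hspa5 at -0.57 ± 0.09 (median -0.19, camera adjusted p = 0.0257; adjusted p = 0.493 with an estimated correlation). This call ended without CBA/J (adjusted p = 0.0864), under quantile normalization (0.0606), with the stricter filter (0.163) and with the array median as a covariate (0.222). Of 27 proteasome subunits, 11 fell and 1 rose (11 and 2 adjusted over the list alone), with Psmd12 at -0.48 ± 0.07 (median -0.07, camera adjusted p = 0.0113; adjusted p = 0.647 with an estimated correlation). This call ended with the stricter filter (adjusted p = 0.105) and with the array median as a covariate (adjusted p = 0.370).

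Interferon-stimulated genes were lower, with 13 of 24 falling and 2 rising (13 and 3 adjusted over the list alone; median -0.52, camera adjusted p = 1.23e-06; adjusted p = 0.160 with an estimated correlation). Rsad2, an antiviral enzyme, fell by 1.08 ± 0.12 and the GTPase Igtp by 0.90 ± 0.09. Acute phase proteins rose in 12 of 24 and fell in 1 (14 and 2 adjusted over the list alone), with Orm1 at 0.48 ± 0.08 and the fibrinogen chain Fgb at 0.40 ± 0.07 (median 0.24, camera adjusted p = 0.00787; adjusted p = 0.493 with an estimated correlation). This call ended without CBA/J (adjusted p = 0.245), under quantile normalization (0.142) and with every probe set on its own (0.186), and Fgb lost its call without CBA/J (0.20 ± 0.08, adjusted p = 0.0846).

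Enzymes that conjugate drugs and steroids rose in 13 of 26 and fell in 3, also adjusted over the list alone (median 0.17, camera adjusted p = 4.57e-05; adjusted p = 0.401 with an estimated correlation). Gstm3 and Nnmt stand in it, and the glucuronosyltransferase Ugt2b35 fell by 0.87 ± 0.07. In bile acid synthesis and transport 8 of 17 fell and 4 rose (10 and 4 adjusted over the list alone; median -0.21, camera adjusted p = 0.00154; adjusted p = 0.460 with an estimated correlation, and 0.0605 with the array median as a covariate), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 0.88 ± 0.11. Of 19 cytosolic ribosomal proteins 4 rose and 0 fell, also adjusted over the list alone (median 0.13, camera adjusted p = 0.0465; adjusted p = 0.715 with an estimated correlation). The ribosomal call ended without B6C3F1/J control replicate 2 (adjusted p = 0.127), under quantile normalization (adjusted p = 0.493) and without CBA/J (adjusted p = 0.208), among other alternatives, with a highest adjusted p of 0.616. In total 14 of 45 lists were higher and 7 lower. Only the fatty acid synthesis, cholesterol, heat shock and female-biased lists, 4 in all, held with an estimated correlation, and fry called 27.

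**Figure D3:**
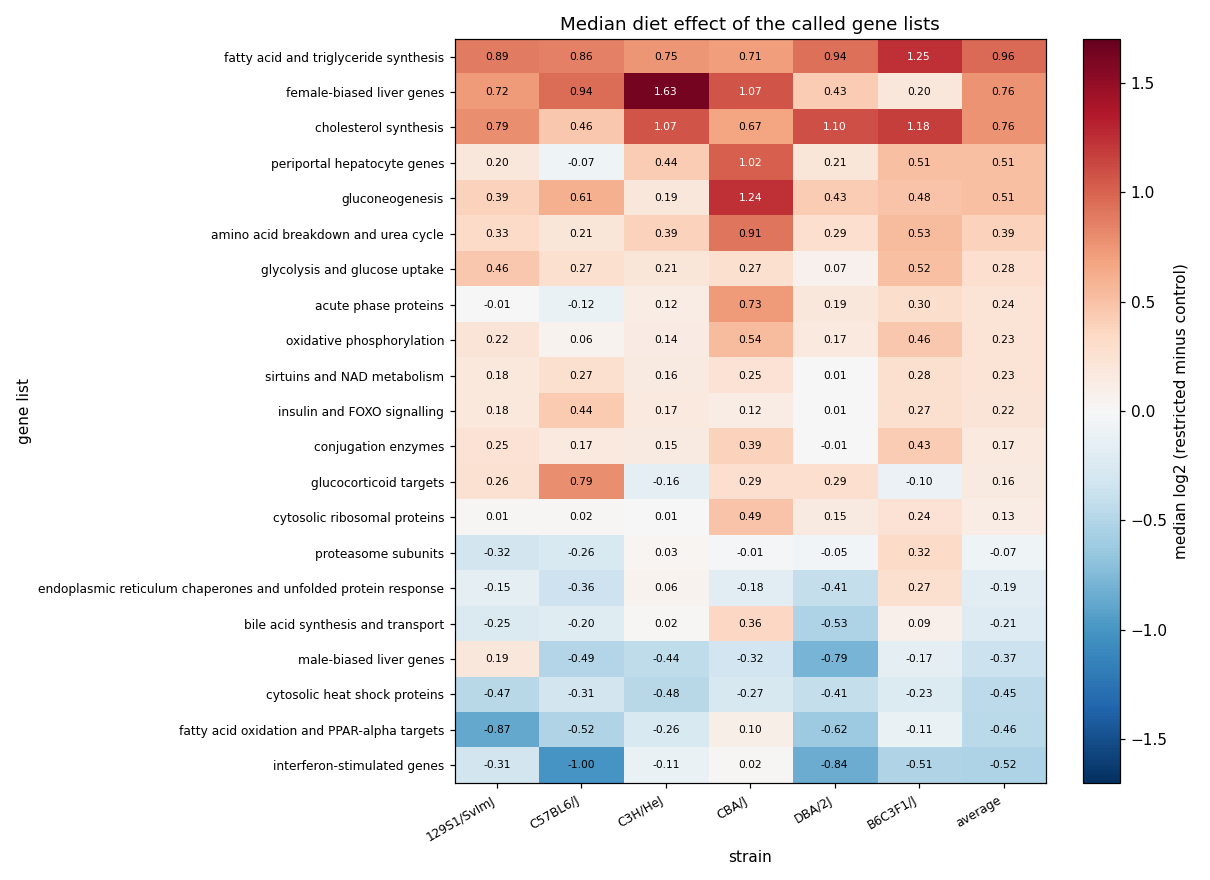
Median log2 difference between restricted and control mice over the measured genes of each called list, by strain and for the average, coloured from blue (lower) to red (higher). Fatty acid and triglyceride synthesis was above 0.70 in every strain. In CBA/J the median difference over all genes was 0.31, and 0.04 with the stricter filter, so lists of bright genes carry less of this shift.

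The remaining process lists were not called. The circadian clock had 4 of 19 genes higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.756), with Clock at -0.57 ± 0.10, Arntl at 0.02 ± 0.22, Per2 at 0.26 ± 0.17 and Dbp at 0.07 ± 0.11. One-carbon, methionine and serine metabolism had 7 of 19 higher and 5 lower (8 and 5 adjusted over the list alone; adjusted p = 0.668), with the folate enzyme Mthfd1 at 0.82 ± 0.07. In the growth hormone and IGF1 axis Igfals, which stabilises circulating IGF1, fell by 0.59 ± 0.10, and 1 of 11 genes rose and 3 fell, also adjusted over the list alone (adjusted p = 0.756). Its test pointed down while its median (0.01) and mean (0.02) were above 0. Igf1 itself differed by 0.21 ± 0.10 (adjusted p = 0.111), its other probe sets included 2 called in the opposite direction, and the call changed to a rise without DBA/2J restricted replicate 6 (0.29 ± 0.07, adjusted p = 0.00122). Cytochrome P450 and nuclear receptor xenobiotic genes had 4 of 19 higher and 5 lower (6 and 5 adjusted over the list alone; adjusted p = 0.988), with Cyp39a1 at 1.39 ± 0.10 and the receptor Nr1i3 at -0.82 ± 0.09. The test of that list pointed down while its median (0.05) and mean (0.13) were above 0, and under quantile normalization it was called lower (adjusted p = 0.0338).

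NRF2 targets had 2 of 13 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.207), with the epoxide hydrolase Ephx1 at -0.78 ± 0.09. Antioxidant enzymes had 3 of 15 higher and 1 lower (5 and 2 adjusted over the list alone; adjusted p = 0.533). Complement and coagulation had 4 of 26 higher and 4 lower (5 and 5 adjusted over the list alone; adjusted p = 0.988), and this list was called lower under quantile normalization (adjusted p = 0.0383). Antigen presentation had 3 of 12 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.518). Lipid droplet and steatosis genes had 3 of 16 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.126), with the lipoprotein receptor Vldlr at 1.07 ± 0.13 and Mogat1, a monoacylglycerol acyltransferase, at -0.97 ± 0.18, with restricted levels below the mean array median in C3H/HeJ, CBA/J and DBA/2J. Lipoproteins and lipid export had 8 of 19 higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.143, and 0.0370 without DBA/2J restricted replicate 6), with the sterol exporter subunits Abcg8 at 0.83 ± 0.11 and Abcg5 at 0.74 ± 0.09.

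The cell cycle list had 2 of 20 genes higher and 1 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.310). Autophagy and lysosome had 5 of 17 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.812), with the protease Ctsl at 0.69 ± 0.08 and Map1lc3a at -0.77 ± 0.07, and its mean (0.02) and median (-0.02) differed in sign. Pericentral hepatocyte genes had 3 of 15 higher and 1 lower (4 and 2 adjusted over the list alone; adjusted p = 0.781). The amino acid response had 5 of 13 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.572), with asparagine synthetase Asns at 1.51 ± 0.22, from control levels below the mean array median in C3H/HeJ, DBA/2J and B6C3F1/J, and Atf5 at -0.84 ± 0.10. The p53 and DNA damage response had 3 of 11 higher and 3 lower (3 and 4 adjusted over the list alone; adjusted p = 0.756), with a median of 0.13 and a mean of -0.01. Of 8 major urinary protein genes 2 were measured, so the list was not tested. Mup3 rose by 0.40 ± 0.08, but another of its probe sets was called in the opposite direction, and it lost its call without CBA/J (0.07 ± 0.09, adjusted p = 0.685). Mup5 fell by 0.48 ± 0.10.

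Markers of other liver cell types showed small shifts. The mean log2 signal of stellate cell and fibroblast markers was 0.20 higher on restriction, in 6 of 6 strains (permutation p = 2e-05, adjusted p = 0.00024 over 12 measures), with Sparc at 0.70 ± 0.08 and Col3a1 at 0.73 ± 0.10. Of these 19 genes 5 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.124). Endothelial markers were 0.15 higher in 6 of 6 strains (permutation p = 0.00037, adjusted p = 0.0022), with the receptor Kdr at 0.63 ± 0.09, and 6 of 19 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.133). In CBA/J the stellate and endothelial scores rose by 0.21 and 0.14, but were -0.10 and -0.18 relative to the median of all genes. Their rise in 6 of 6 strains thus depends on the scaling of CBA/J, and both permutation p values include its shift. Kupffer cells and macrophages had 2 of 19 higher and 0 lower (0 and 0 adjusted over the list alone; adjusted p = 0.518), and lymphocytes 0 of 14 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.609). Bile duct cells had 1 of 6 higher and 0 lower (0 and 0 adjusted over the list alone; adjusted p = 0.522), and pancreatic acinar cells 1 of 7 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.660). Erythroid cells had 0 of 3 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.276), adipocytes 0 and 0 of 3 (adjusted p = 0.775) and skeletal muscle 0 and 0 of 8 (adjusted p = 0.518), the last pair also 0 and 0 adjusted over the list alone. The erythroid and adipocyte tests pointed down with means of -0.09 and -0.11 while their medians were 0.02 and 0.03.

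A shared response was seen in 26 genes that were called in the same direction in each of the 6 strains, 18 higher and 8 lower. Besides Nnmt, Gstm3, Acacb, Acss2, Pmvk, Acaca, Nsdhl, Lss and Pgam1, the rises included Dhcr7 of cholesterol synthesis (1.497 ± 0.14), the amino acid transporter subunit Slc3a1 (1.36 ± 0.08), Aldoc (1.19 ± 0.07), the glutathione transferases Gstm6 (1.18 ± 0.11) and Gstm2 (1.05 ± 0.09), and Slc25a12, the mitochondrial aspartate carrier (0.77 ± 0.06). The falls were in Serpina4-ps1, Csad, Vnn1, Hsp90aa1, Ugt2b35, the liver transcription factor Foxa3 (-1.06 ± 0.08), the haem synthesis enzyme Cpox (-0.98 ± 0.10) and Hdhd3 (-0.82 ± 0.08). Genes not named elsewhere in this group were picked because of their membership. If calls in the strains were independent, 1.64e-05 rises and 5.01e-06 falls would have been reached by chance. The count was 43 without B6C3F1/J control replicate 2 and 42 without DBA/2J restricted replicate 6, and 14 with arrays centred on their 75th percentile, and 81 without both of these arrays. In 5 strains 57 genes were called with the same sign, in 4 strains 131, and in a single strain 6020, while 208 genes rose in some strain and fell in another.

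Within strains, the count of changed genes ranged from 289 in C3H/HeJ to 6023 in CBA/J. The diet effects of pairs of strains correlated across genes with r from -0.01 to 0.30 in the 10 pairs without CBA/J (median 0.236) and from -0.04 to 0.33 in the 5 pairs with it. Genes are not independent replicates in these values. Of the genes called in a strain, 65.7% to 96.5% had the same sign in another strain among the 10 pairs without CBA/J, and 50.8% to 78.0% in pairs with it.

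**Figure D4:**
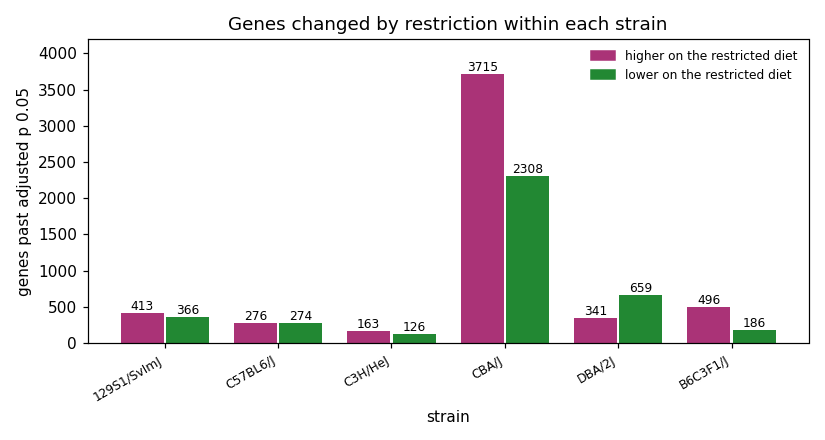
Number of genes higher (purple) and lower (green) on the restricted diet at an adjusted p under 0.05 in each strain, over 14816 genes and 8 mice per diet. CBA/J had 3715 higher and 2308 lower genes, and the other 5 strains had 289 to 1000 in total. The order of these other strains depends on the spread estimate shared by all groups.

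In 129S1/SvImJ the response was led by a fall of fatty acid oxidation. Of its 30 genes 16 fell and 0 rose (21 and 0 adjusted over the list alone; median -0.87, camera adjusted p = 4.46e-38, and 0.00190 with an estimated correlation), among them the peroxisomal enzyme Ehhadh (-2.56 ± 0.22) and Acot1, which was 13.0-fold lower (-3.70 ± 0.45, adjusted p = 1.54e-09). Csad was 10.2-fold lower (-3.35 ± 0.28). Gstm3 rose 12.4-fold (3.63 ± 0.40) and Gnat1, a transducin subunit of rod cells, 14.2-fold (3.83 ± 0.48), from a control level of 4.34 ± 2.03 (SD) that lay below the mean array median of 6.79. In this strain 413 genes rose and 366 fell. The total was 504 with arrays centred on their 75th percentile and 1387 without the 2 outlying arrays, a choice made after the data were seen.

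In C57BL6/J Cyp2b9 rose 35.1-fold (5.14 ± 0.61, adjusted p = 2.53e-09) and Gstm3 9.94-fold (3.31 ± 0.40), while Cidea, a lipid droplet protein of fatty liver, was 19.2-fold lower (-4.26 ± 0.77) and Hsd3b5 16.8-fold lower (-4.07 ± 0.50). The restricted level of Cidea, 4.57 ± 1.498 (SD), lay below the mean array median of 6.38, so the size of its fold is uncertain. Cidec, a related droplet protein, fell by 2.48 ± 0.40. In the average of strains it differed by -0.22 ± 0.16, and without CBA/J by -0.59 ± 0.16 (adjusted p = 0.00497). The 3' minus 5' signal of beta-actin was 0.25 higher on restriction in C57BL6/J (exact permutation p = 0.0012, adjusted p = 0.013). Here 7 lists held with an estimated correlation. On the higher side were fatty acid and triglyceride synthesis (median 0.86, 10 of 21 higher), female-biased genes (0.94, 6 of 15 higher), glucocorticoid targets (0.79, 8 of 16 higher) and insulin and FOXO signalling (0.44, 5 of 15 higher). Interferon-stimulated genes (median -1.0, 10 of 24 lower), lipid droplet genes (-0.63, 4 of 16 lower and 1 higher) and male-biased genes (-0.49, 5 of 16 lower) were on the lower side. Adjusted over the list alone, the counts in that order were 14, 6, 10, 8, 16, 8 with 1 higher, and 6. The Kupffer cell marker score was 0.60 lower (exact permutation p = 0.037, adjusted p = 0.15) and that of lymphocytes 0.54 lower (exact permutation p = 0.011, adjusted p = 0.064). In total 276 genes rose and 274 fell. The total was 1533 when the 16 arrays of the strain were fitted alone, 332 with arrays centred on their 75th percentile and 1066 without the 2 outlying arrays.

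In C3H/HeJ the female-biased gene Cyp2b13 rose 76.5-fold (6.26 ± 0.68, adjusted p = 4.43e-11), from a control level of 4.57 ± 2.05 (SD) below the mean array median of 6.41, and Nnmt rose 29.4-fold (4.88 ± 0.40). Serpina4-ps1 was 20.04-fold lower (-4.33 ± 0.55) and Vnn1 4.25-fold lower (-2.09 ± 0.26). Cholesterol synthesis (median 1.07, 11 of 20 higher), female-biased genes (1.63, 5 of 15 higher) and male-biased genes (-0.44, 4 of 16 lower) held with an estimated correlation (adjusted p = 0.0104, 1.42e-07 and 0.0396). Adjusted over the list alone, the counts were 15, 6 and 6. In total 163 genes rose and 126 fell. The total was 1077 when the arrays of the strain were fitted alone, 172 with arrays centred on their 75th percentile and 607 without the 2 outlying arrays.

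In CBA/J the median diet difference over all genes was 0.31, and it was 0.07 after quantile normalization, so values are also given relative to the 0.31. The median was 0.04 with the stricter filter and 0.50 with no filter on dim probe sets, so the shift was smaller among bright genes. A value relative to the median is therefore no exact correction for a bright or a dim gene. Henmt1 rose by 3.92 ± 0.84 (3.60 relative to the median of all genes) and Gm32743 by 3.79 ± 0.69 (3.48), while Sh3bgrl fell by 3.72 ± 0.34 (-4.03) and Cks1b, a cell cycle kinase subunit, by 3.35 ± 0.45 (-3.67). The control levels of Henmt1 and Gm32743, 3.68 ± 1.99 and 4.09 ± 1.18 (SD), lay below the mean array median of 6.52, and the restricted level of Cks1b, 6.43 ± 1.51 (SD), below that of 7.29, so the sizes of these changes are uncertain. Lipoproteins and lipid export had 12 of 19 genes higher and 2 lower (median 0.80 relative to all genes, camera adjusted p = 0.000760), gluconeogenesis 9 of 12 higher and 1 lower (0.92, adjusted p = 0.0114) and amino acid breakdown 16 of 26 higher and 2 lower (0.59, adjusted p = 0.000172). Adjusted over the list alone, the counts were 13 and 2, 9 and 1, and 16 and 2. No list held with an estimated correlation (lowest adjusted p = 0.973). Marker scores of lymphocytes, bile duct cells, pancreatic acinar cells and skeletal muscle were 1.11, 1.21, 1.14 and 1.33 higher in the restricted group (exact permutation adjusted p = 0.0028, 0.018, 0.0028 and 0.011), or 0.79, 0.90, 0.83 and 1.02 relative to the median of all genes. The control means of these scores, 4.52 to 6.27, lay below the mean array median of 6.52, and on the same arrays the median was 0.77 and the 3' minus 5' signal of Gapdh 0.37 higher on restriction. In total 3715 genes rose and 2308 fell, but after quantile normalization 2013 rose and 2549 fell, so the direction of the balance depends on the scaling.

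In DBA/2J Nnmt rose 22.7-fold (4.50 ± 0.40, adjusted p = 1.29e-14) and Cyp2b9 16.1-fold (4.01 ± 0.61), the latter from a control level of 6.78 ± 2.50 (SD) at the mean array median of 6.78. Serpina12 was 15.6-fold lower (-3.97 ± 0.41) and Obp2a, an odorant-binding lipocalin, 7.62-fold lower (-2.93 ± 0.53). Male-biased genes had 7 of 16 lower (median -0.79) and female-biased genes 6 of 15 higher (0.43), and both held with an estimated correlation (adjusted p = 0.0389 and 0.00844). Adjusted over the list alone, the counts were 9 and 7. In total 341 genes rose and 659 fell. Without DBA/2J restricted replicate 6 the counts were 335 and 415, the total was 137 when the arrays of the strain were fitted alone, and the median of all genes was 0.03 as deposited and -0.07 after quantile normalization.

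In B6C3F1/J Cyp2b13 rose 53.02-fold (5.73 ± 0.68, adjusted p = 6.95e-10), from a control level of 5.45 ± 2.01 (SD) below the mean array median of 6.90, and Fasn 15.1-fold (3.92 ± 0.58), while Hsd3b5 was 14.1-fold lower (-3.82 ± 0.50) and Ptprr, a receptor phosphatase, fell by 3.34 ± 0.81. Ptprr lay below the mean array median on both diets, at 6.48 ± 1.31 and 3.14 ± 1.52 (SD), so no fold is given. Fatty acid and triglyceride synthesis had 16 of 21 genes higher (median 1.25) and cholesterol synthesis 13 of 20 (1.18), and both held with an estimated correlation (adjusted p = 0.00157 and 0.0275). Adjusted over the list alone, the counts were 17 and 17. The median of all genes was 0.00 as deposited and 0.13 after quantile normalization. In total 496 genes rose and 186 fell. Without B6C3F1/J control replicate 2 the counts were 241 and 233, and the total was 157 when the arrays of the strain were fitted alone.

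The response differed between strains for 3534 genes in the interaction test, and for 229 when CBA/J was left out. The 8 genes with the smallest p were Apoa2, an apolipoprotein of high-density lipoprotein, Pcyox1, Hnrnpf, Vma21, Caprin1, Acsl4, Cpeb4 and Ehhadh, with adjusted p from 1.64e-11 to 2.14e-10. Apoa2 rose by 1.80 ± 0.16 in CBA/J (1.49 relative to the median of all genes) and differed by -0.39 to 0.18 elsewhere. It lost its call under quantile normalization (adjusted p = 0.311). The genes Pcyox1, Hnrnpf, Vma21, Caprin1, Acsl4 and Cpeb4 fell by 1.97 to 2.79 in CBA/J, against the median shift of 0.31. Acsl4, an acyl-CoA synthetase, rose by 1.28 ± 0.26 in 129S1/SvImJ. Without CBA/J none of these 7 genes was called (adjusted p from 0.410 to 0.889), whereas Ehhadh, which differed from -2.56 ± 0.22 in 129S1/SvImJ to 0.15 ± 0.22 in B6C3F1/J, was (adjusted p = 7.13e-09).

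Some gene groups responded differently in 1 strain from the mean of the other 5, and held with an estimated correlation. In 129S1/SvImJ fatty acid oxidation genes fell further, with a median difference of -0.54 and 9 of 30 lower (19 adjusted over the list alone; camera adjusted p = 2.21e-25, and 0.0310 with an estimated correlation). In C57BL6/J the diet effect was higher than in the mean of the other 5 for glucocorticoid targets (median difference 0.50, 2 of 16 higher) and insulin and FOXO signalling (0.44, 1 of 15). It was lower for interferon-stimulated genes (-0.80, 8 of 24 lower), antigen presentation (-0.68, 3 of 12), lipid droplet genes (-0.48, 3 of 16) and Kupffer cell markers (-0.85, 3 of 19). This need not be a larger fall, since the Kupffer cell score fell by 0.60 in C57BL6/J but was 0.09 to 0.42 higher in the other strains. Adjusted over the list alone, the counts were 5, 3, 14, 6, 6 and 13. Their adjusted p with an estimated correlation were 0.02497, 0.0487, 0.02497, 0.0302, 0.02497 and 0.0398. Igtp fell by 1.73 ± 0.21 in C57BL6/J, and Cd74, which carries class II molecules, by 1.25 ± 0.35.

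The signals of many genes differed between strains on the control diet. Dct, a melanin synthesis enzyme, was 87.5-fold lower in 129S1/SvImJ than the mean of the other 5 strains (-6.45 ± 0.24, adjusted p = 3.57e-41), and Cox6b2, a cytochrome oxidase subunit, was 70.5-fold higher (6.14 ± 0.47). Sult1e1, an oestrogen sulfotransferase, was 40.5-fold higher in 129S1/SvImJ and Mme, the peptidase neprilysin, 33.7-fold lower. The inflammasome gene Nlrp12 (49.8-fold) and Cidea (26.4-fold) were higher in C57BL6/J, and Crym (26.5-fold) and Elobl (20.2-fold) lower. In C3H/HeJ the cholesterol hydroxylase Cyp46a1 (12.01-fold) and the growth factor Hbegf (9.63-fold) were higher, and Cyp17a1 (12.9-fold) and the class I gene H2-D1 (11.9-fold) lower. Many of these folds rest on a dim side, so their size is uncertain. Dct and Mme were at 5.05 ± 1.23 and 5.54 ± 2.02 (SD) in 129S1/SvImJ, below its mean array median of 6.79. Cox6b2 and Sult1e1 were below the mean array median in the other 5 strains (5.47 to 6.41 and 3.75 to 5.53), as was Cidea in all but C57BL6/J and Nlrp12 in all but C57BL6/J and B6C3F1/J. Crym and Elobl lay below it in C57BL6/J and Cyp17a1 in C3H/HeJ, and Hbegf lay below it in 129S1/SvImJ, CBA/J and DBA/2J.

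Meox2 (57.6-fold) and Serpina3a (23.1-fold) were higher in CBA/J, and Mndal (23.8-fold) and the deiodinase Dio1 (23.3-fold) lower. In DBA/2J Obp2a (37.7-fold) and Mrap2 (19.2-fold) were higher, and Ildr2 (34.2-fold) and Gm19696 (20.7-fold) lower. In B6C3F1/J Cyp2b9 (17.1-fold) and Nlrp12 (8.56-fold) were higher, and Orm3 (7.46-fold) and Scara5 (4.64-fold) lower. Scara5 lost its call with the mean of its probe sets (-1.18 ± 0.42, adjusted p = 0.0595). Meox2 and Mrap2 lay below the mean array median in the other 5 strains, Serpina3a in all but CBA/J and DBA/2J, and Mndal in CBA/J. Obp2a lay below it in C57BL6/J, C3H/HeJ and B6C3F1/J, and Cyp2b9 in 129S1/SvImJ and DBA/2J. Ildr2 and Gm19696 lay below it in DBA/2J, and Orm3 and Scara5 in B6C3F1/J, so the size of these folds is uncertain too. The test over the 6 control groups called 6467 genes. The 15 pairs of strains had 28124 calls in total, from 745 between C3H/HeJ and B6C3F1/J to 2235 between DBA/2J and B6C3F1/J. Of the calls between C57BL6/J and the other 4 inbred strains, 44.8% to 54.6% were higher in C57BL6/J. Among genes with several called probe sets, a median of 9.66% over the 15 pairs had probe sets called in opposite directions, so part of these differences depends on the probe set.

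On the control diet B6C3F1/J departed from the mean of its parents C57BL6/J and C3H/HeJ, which tests whether the cross lies midway between them in log2 signal. Where the parents differ, a cross at the mean of their linear signals would lie above this midpoint. Cyp2b9 was higher in the cross by 2.84 ± 0.53 (adjusted p = 0.000247), at 12.22 ± 0.92 (SD) against 7.31 ± 1.01 in C57BL6/J and 11.46 ± 1.62 in C3H/HeJ. The transcript Csmd2os (2.76 ± 0.72) and the muscle gene Cmya5 (2.71 ± 0.76) were also higher, and the acute phase gene Orm3 (-2.57 ± 0.55), Cidea (-2.25 ± 0.67) and the trefoil factor Tff3 (-1.93 ± 0.40) were lower. The signals of Csmd2os, Cmya5 and Orm3 lay below the mean array median in all 3 strains, as did Cidea in C3H/HeJ and B6C3F1/J. Csmd2os and Cmya5 lost their call with the array median as a covariate (adjusted p = 0.112 and 0.179). The skeletal muscle marker score was 6.80 ± 2.97 (SD) in B6C3F1/J controls, with a highest value of 11.86, against 4.35 ± 0.39 in C57BL6/J and 6.34 ± 2.99 in C3H/HeJ. In total 403 genes were higher and 922 lower than the parental mean. Without B6C3F1/J control replicate 2 the counts were 335 and 451, and Cmya5 lost its call (adjusted p = 0.0816). The balance turned with the array median as a covariate, to 362 higher and 279 lower, and was 598 and 607 without both outlying arrays.

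The diet effect in B6C3F1/J differed from the mean effect of its parents for a single gene in limma. Fhad1 fell by 2.75 in B6C3F1/J, while it differed by 1.59 in C57BL6/J and by -0.16 in C3H/HeJ, which gave a difference of -3.47 ± 0.69 (adjusted p = 0.0305). In B6C3F1/J its signal lay below the mean array median on both diets, at 6.61 ± 0.87 and 3.86 ± 0.89 (SD). No gene was higher, so the counts were 0 and 1, and 1033 genes had an unadjusted p under 0.05 in the same limma test. Fhad1 lost its call without B6C3F1/J control replicate 2 (-3.38 ± 0.70, adjusted p = 0.0824) and under quantile normalization (-3.17 ± 0.66, adjusted p = 0.0756). Without DBA/2J restricted replicate 6 the count was 2.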

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

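The tests of array scaling in CBA/J and of slopes on the same 4 strains, the test of the share of calls higher in C57BL6/J, and all tests of the balance of calls in B6C3F1/J were chosen only after the result was seen.

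CBA/J had 6023 genes changed by the diet, against at most 1000 in other strains, and array scaling is argued against as the whole cause, because 4562 genes were still called after quantile normalization, when no other strain had more than 975. The signals showed no uniformly larger form of the shared response. The CBA/J effect followed the average of the other 5 strains with a slope of 0.6765 (95% bootstrap interval 0.6265 to 0.7356). The others had slopes of 0.7053 to 0.8439, each on 4 strains and its own genes. Lower quality of the restricted CBA/J arrays could itself lower the slope, so it cannot exclude a larger response in the mice. The bootstraps drew genes and not mice, so the intervals leave out the spread between mice. On the same 4 strains and genes the CBA/J slope differed by -0.2003 (-0.2711 to -0.1304) from that of 129S1/SvImJ, and the smallest difference was -0.05923 (-0.1334 to 0.01799) from B6C3F1/J. RNA, labelling or hybridisation quality of the CBA/J restricted arrays is a candidate explanation that stays open. In CBA/J 24.91% of genes with several called probe sets had them called in opposite directions, against at most 2.817% in the diet contrasts of the other strains. That share rests on 1867 genes in CBA/J and on 46 to 213 in each other strain. It was computed on the signals as deposited and not again after quantile normalization. The shift was smaller among bright genes, so scaling that varies with brightness could also raise the share. It thus cannot tell quality from such scaling. The signal of the CreX spike-in control was 15.701 to 16.975 in the restricted CBA/J arrays, against 15.223 to 15.684 in their controls. In 129S1/SvImJ this signal also parted the diets but the other way, at 15.681 to 16.759 in controls and 15.092 to 15.54 in restricted arrays. There the array median differed by only 0.03. A high CreX signal is thus not particular to the shifted arrays. A spike-in does not come from the mice, so a technical part in these differences is possible, but they were not tested. A response particular to CBA/J beside a technical part also stays open, since it was not tested and all 8 restricted CBA/J arrays share the shift.

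Strain differences on the control diet were large and many, with 28124 calls over 15 pairs. Probes built on the C57BL6/J sequence that read other strains lower stay open, because over the 4 pairs of C57BL6/J with another inbred strain a median of 51.93% of all calls, but 57.46% of calls of at least 4-fold, was higher in C57BL6/J, and the scaling of arrays to 1 level could hide part of such a loss. Sequence variants under single probes may contribute, because a median of 9.661% of genes with several called probe sets had them called in opposite directions, above the 2.817% that was the highest in the diet contrasts without CBA/J. Inherited differences in expression between strains stay open and were not tested apart from such variants.

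Genes that set B6C3F1/J apart from the mean of its parents on the control diet leaned to the lower side, at 69.58% of calls. The outlying array B6C3F1/J control replicate 2 could account for the lean at least in part, since the share was 57.38% without it and 50.37% without both outlying arrays. Scaling between arrays stays open as well, because the share was 76.8% after quantile normalization and 79.02% with arrays centred on their 75th percentile, but 43.53% with the array median as a covariate. With quantile normalization and without both outlying arrays it was 47.55%. An effect of the cross itself stays open and was not tested.

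A few arrays stood apart from the other 7 of their group. The median log2 signal was 8.295 in DBA/2J restricted replicate 6 and 8.655 in B6C3F1/J control replicate 2. The 3' minus 5' signal of Gapdh was 0.251 in C3H/HeJ control replicate 8, 2.514 in DBA/2J restricted replicate 6 and 0.103 in B6C3F1/J control replicate 2. That of beta-actin was 1.559 in C3H/HeJ control replicate 8 and 4.856 in DBA/2J restricted replicate 6. The 18S ribosomal RNA control signal was 15.946 in 129S1/SvImJ control replicate 2. It was also high, though not flagged, in C3H/HeJ control replicates 5 and 8 (13.995 and 14.072) and restricted replicates 1 and 5 (13.844 and 14.043). Over the 228 tests of a measure or gene within a group 26 values stood apart, where chance gives about 1 in 20 tests, or 11.4. Some arrays stood apart in several tests, such as DBA/2J restricted replicate 6 and B6C3F1/J control replicate 2. The tests are therefore not independent, and 26 is not a count of arrays.

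Marker scores of single arrays stood apart in several groups. The score of Kupffer cells and macrophages was 9.116 in C57BL6/J control replicate 1, lower than its group, and 11.665 in C3H/HeJ restricted replicate 4, higher. The endothelial score was low in CBA/J control replicate 2 at 8.975 and in B6C3F1/J control replicate 2 at 8.627. The adipocyte score was 5.372 in 129S1/SvImJ restricted replicate 2, below its group. The skeletal muscle score was 8.38 in 129S1/SvImJ restricted replicate 4 and 12.658 in B6C3F1/J restricted replicate 2, both above their groups.

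Single mice also stood apart for the genes with the largest diet effects. Nnmt was 14.07 in C57BL6/J restricted replicate 2 and 14.286 in C3H/HeJ restricted replicate 4, both above their groups. Gstm3 was 13.816 in C3H/HeJ control replicate 6, Cyp2b13 was 7.259 in DBA/2J control replicate 4 and Serpina4-ps1 was 9.238 in C3H/HeJ restricted replicate 6, each above its group. Hsd3b5 was 13.039 in DBA/2J control replicate 1, below its group. Serpina12 was 6.316 in 129S1/SvImJ control replicate 6, 4.95 in DBA/2J restricted replicate 6 and 9.348 in B6C3F1/J control replicate 2, all below their groups. It was above its group in C57BL6/J restricted replicate 2 at 11.656 and in C3H/HeJ restricted replicate 1 at 12.491.

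The diet effect of 8 genes differed between strains by the interaction test. Between the strains with the highest and lowest effect the log2 difference was 2.191 for Apoa2 (CBA/J against 129S1/SvImJ), 2.456 for Pcyox1 (C3H/HeJ against CBA/J), 2.574 for Hnrnpf (DBA/2J against CBA/J) and 2.272 for Vma21 (C57BL6/J against CBA/J). It was 2.969 for Caprin1 and 2.805 for Cpeb4 (both C3H/HeJ against CBA/J), 3.25 for Acsl4 (129S1/SvImJ against CBA/J) and 2.711 for Ehhadh (B6C3F1/J against 129S1/SvImJ). In CBA/J other probe sets of Pcyox1, Hnrnpf, Caprin1 and Acsl4 reached 0.06, 0.24, 0.02 and 0.24, and these were not called.

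Gene lists responded differently in single strains than in the mean of the other 5. The median difference was -0.54 for fatty acid oxidation and PPAR-alpha targets in 129S1/SvImJ. In C57BL6/J it was 0.50 for glucocorticoid targets, 0.44 for insulin and FOXO signalling, -0.80 for interferon-stimulated genes, -0.68 for antigen presentation, -0.48 for lipid droplet genes and -0.85 for Kupffer cells and macrophages. Among 6126 kept probe sets without a single gene symbol, which stand in no comparison of genes, 882 passed the threshold for the averaged diet effect, 489 higher and 393 lower.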

How the results depend on the processing

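The alternatives that left out the 2 outlying arrays, used the array median as a covariate, or left out CBA/J were chosen after the data were seen. Of 233 recomputed counts 181 stayed within 1.5 times the reported count. Of 715 recomputed list tests 677 kept their side of the threshold, as did 3321 of 3408 for named genes, where 68 lost and 18 gained a call. Among these, results that stayed called also kept their direction, while the direction of results not called was not compared. Of 128 interaction tests of named genes 119 kept their call. The 4 lists that held with an estimated correlation kept their camera call at the preset correlation under all alternatives run. Camera with an estimated correlation was not repeated under the alternatives, so whether that result holds there was not tested. The cause of the changes below was not tested, except where fewer or more probe sets, genes or arrays were tested by construction.

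Under quantile normalization the number of genes whose diet effect in B6C3F1/J differed from its parents was 0. The adjusted p of lists was 0.0338 for cytochrome P450 genes, 0.0606 for endoplasmic reticulum chaperones, 0.142 for acute phase proteins, 0.493 for ribosomal proteins and 0.0383 for complement and coagulation, which turned to lower. Of the 4086 genes of the averaged effect 3065 kept their call and 1 was called in the opposite direction. With arrays centred on their 75th percentile the counts were 504 in 129S1/SvImJ, 332 in C57BL6/J, 172 in C3H/HeJ and 14 for all 6 strains, and the ribosomal list had 0.156. In CBA/J this centring gave 2641 higher and 2615 lower. With the offset the ribosomal list had 0.0510 and B6C3F1/J against its parents had 0 for the diet effect. With the stricter filter that count was 0, and the adjusted p was 0.163 for endoplasmic reticulum chaperones, 0.0509 for ribosomal proteins and 0.105 for the proteasome.

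With the mean of a gene's probe sets Mup3 turned to -0.19, and the adjusted p was 0.314 for ribosomal proteins, 0.0824 for insulin and FOXO signalling and 0.0212 for endothelial cells. With every probe set on its own more features were tested. The counts were 7501 for the average, 827 in C57BL6/J, 11742 in CBA/J, 1775 in DBA/2J, 1086 in B6C3F1/J, 6164 for the interaction, 11804 for strain differences, 49524 over pairs, 2406 for B6C3F1/J against its parents on the control diet and 0 for the diet effect. The adjusted p was 0.0102 for NRF2 targets, 0.08 for glucocorticoid targets, 0.186 for acute phase proteins, 0.616 for ribosomal proteins, 0.159 for insulin and FOXO signalling, 0.00706 for endothelial cells and 0.0156 for stellate cells.

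With limma arrayWeights the counts were 1513 in 129S1/SvImJ, 3085 in C57BL6/J, 1407 in C3H/HeJ, 1152 in B6C3F1/J, 103 for all 6 strains, 52678 over pairs and 26 for the diet effect in B6C3F1/J against its parents. When only the groups of a contrast were fitted they were 1533 in C57BL6/J, 1077 in C3H/HeJ, 137 in DBA/2J, 157 in B6C3F1/J, and 846 and 4 for B6C3F1/J against its parents on the control diet and for the diet effect. At least 1.5-fold, 877 genes changed on average and 865 set B6C3F1/J apart. With a block for replicate number the count for the diet effect in B6C3F1/J against its parents was 0. Residuals of control and restricted arrays with the same number correlated with r from -0.171 to 0.140, so the numbers were not read as pairs.

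Without both outlying arrays the counts were 1387 in 129S1/SvImJ, 1066 in C57BL6/J, 607 in C3H/HeJ and 81 for all 6 strains. Neither array belongs to 129S1/SvImJ, C57BL6/J or C3H/HeJ, so their counts moved through the shared spread and not through their own arrays. With quantile normalization as well the counts were 1424, 1085, 619 and 93, and the adjusted p was 0.189 for acute phase proteins, 0.0450 for lipid droplet genes, 0.304 for ribosomal proteins and 0.04655 for endothelial cells. Without B6C3F1/J control replicate 2 the counts were 43 for all 6 strains, and 786 and 0 for B6C3F1/J against its parents on the control diet and for the diet effect, and the adjusted p was 0.127 for ribosomal proteins, 0.0520 for insulin and FOXO signalling and 0.364 for lipoproteins. Without DBA/2J restricted replicate 6 the counts were 42 for all 6 strains, and 1729 and 2 for B6C3F1/J against its parents on the control diet and for the diet effect. The adjusted p was then 0.0370 for lipoproteins, 0.00657 for ribosomal proteins and 0.0129 for insulin and FOXO signalling.

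With the array median as a covariate the counts were 436 in C3H/HeJ, 43 for all 6 strains, 641 for B6C3F1/J against its parents on the control diet, 362 higher and 279 lower, and 0 for the diet effect, and DBA/2J had 538 higher and 500 lower. The adjusted p was 0.0605 for bile acid genes, 0.01396 for antioxidant enzymes, 0.222 for endoplasmic reticulum chaperones, 0.0139 for lipoproteins, 0.370 for the proteasome and 0.0182 for endothelial cells. With CBA/J left out fewer arrays were tested. The counts were 2589 for the average and 229 for the interaction, and the adjusted p was 0.0864 for endoplasmic reticulum chaperones, 0.245 for acute phase proteins, 0.0133 for lipid droplet genes, 0.208 for ribosomal proteins and 0.0313 for stellate cells.

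In simulated data with the same number of arrays 64.2%, 89.6% and 100% of genes changed by a log2 of 0.5, 1 and 2 were found in the average of strains. In single strains 7.46% to 13.4%, 38.8% to 50.8% and 69.7% to 86.4% were found, so many simulated genes changed by a log2 of 1 were missed in a single strain. The simulated genes were independent, with the same spread in all groups, so the share missed in the real data was not measured. The signal over background of dim genes limits detection further.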

Other observations

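The values without B6C3F1/J control replicate 2 were chosen only after the result was seen.

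Markers of other cell types differed with diet in single strains as well. The endothelial score was 0.24 higher in restricted C57BL6/J mice (exact permutation p = 0.00093, adjusted p = 0.011) and 0.29 higher in restricted B6C3F1/J mice (exact permutation p = 0.0057, adjusted p = 0.046). Without B6C3F1/J control replicate 2 the latter was 0.16 (exact permutation p = 0.009, adjusted p = 0.059), so it no longer passed. Markers of skeletal muscle varied widely between mice within groups, with an SD of 2.99 in C3H/HeJ controls and 2.97 in B6C3F1/J controls.

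Genes of fatty acid and triglyceride synthesis and of cholesterol synthesis may shift together in single mice. After group means were removed, their mean scores correlated over 96 mice with a Pearson r of 0.7912 and a Spearman rho of 0.743 (permutation p = 1e-05 for both, the smallest the draws can give; adjusted p = 0.000015 and 3e-05 over 3 relations). Without the 2 farthest arrays r was 0.713. Scores of female-biased and male-biased genes correlated with an r of -0.458 (permutation p = 1e-05, adjusted p = 0.000015) and a rho of -0.413 (permutation p = 8e-05, adjusted p = 0.00012), and r was -0.413 without the 2 farthest arrays, which is consistent with opposite shifts in the same mice. The scores of fatty acid synthesis and of fatty acid oxidation had an r of 0.1592 (permutation p = 0.2) and a rho of -0.09 (permutation p = 0.39), and r was -0.18 without the 2 farthest arrays, so opposite shifts in the same mice were not seen for this pair.

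Diet or strain labels were drawn again among the same arrays, with 100 splits for each result including the real one. The real split alone, 1 of 100, gave as many genes for the averaged diet effect (4086, highest other 190) and for all 6 strains (26, highest other 0). The same held in 129S1/SvImJ (779, highest other 108), C57BL6/J (550, highest other 5), C3H/HeJ (289, highest other 76), CBA/J (6023, highest other 2799), DBA/2J (1000, highest other 834) and B6C3F1/J (682, highest other 450). It also held for strain differences on the control diet (6467, highest other 124), for pairs of strains (28124, highest other 1812), for B6C3F1/J against its parents on the control diet (1325, highest other 931) and for the interaction once main effects were removed (3477, highest other 2). For each of these the share of splits with as many genes was under 0.05, which was not adjusted over the results. This bears on the total and not on single calls. In CBA/J, DBA/2J, B6C3F1/J and the cross against its parents, another split alone gave 2799, 834, 450 and 931 genes. The totals there do not show how many of the calls are due to diet or strain. For gene lists under the diet 4 of 100 splits called as many lists as the real 21, with a highest other of 23. For the diet effect in B6C3F1/J against its parents 3 of 100 gave as many genes as the real 1, with a highest other of 2. Both shares are under 0.05, but in each case another split gave more than the real one, and the count in B6C3F1/J was 0 under quantile normalization and with the stricter filter.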
